A study of Mus musculus with 10 samples.

How the data were processed

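RNA came from in vivo matured MII oocytes of B6D2F1 mice given equine and then, 48 h later, 5 IU of human chorionic gonadotropin. Per the labels' protocols, oocytes were collected 16 h after the second hormone, freed of cumulus cells with hyaluronidase, and either kept intact or separated by microsurgery. Up to 50 ng of total RNA went through 2 rounds of cDNA synthesis and amplification, and 10 µg of biotin-labelled cRNA were hybridised to Affymetrix arrays, per the labels' protocols. The 10 arrays were 3 of the SCC (replicates 1 to 3), 4 of the cytoplast (1 to 4) and 3 of the MII oocyte (2 to 4), grouped by their titles.

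The deposited value table holds intensity values on a linear scale for 45101 probe sets. RMA, which corrects background, normalizes and summarises probes to probe sets, was named in the submitters' processing notes; its version and settings are not given in the sources used here, and scanner files were not used here. The array medians and the upper percentiles still differed between arrays. The test plan had assumed log2 values, so log2 was taken first and the tests were otherwise run as planned. With 2 rounds of amplification and a fixed amount of cRNA per array, the values are relative amounts within a sample, not amounts per oocyte.

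Besides 64 controls, 34945 probe sets were listed with 1 gene, 932 with several and 9160 with none. Of those with 1 gene, 34754 matched by gene ID to the RefSeq gene table of the GRCm38.p6 assembly, used only for names and for the span of genes. No gene was named from a probe set with several genes, and no coordinates are given because the build behind the platform annotation is not given in the sources used here. Probe sets were kept if they lay above the array's median on at least 3 arrays (23737). The gene-level value was that of the kept single-gene probe set with the highest mean over all arrays (12713 genes).

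Differences were tested with limma 3.58.1 in R 4.3.3, with 1 mean per group over all 10 arrays, default moderation and Benjamini-Hochberg adjustment, at a threshold of 0.05. Adjusted p-values of genes are over the 23737 probe sets. 18 gene lists were fixed before the data were examined: spindle assembly and motors, tubulins, microtubule organising centre, kinetochore and checkpoint, cohesin and condensin, meiotic cell cycle, translation initiation, mRNA storage and decay, ribosomal proteins, oxidative phosphorylation, proteasome, oocyte-specific genes, chromatin, actin cortex, endoplasmic reticulum, DNA replication and repair, cumulus cells and genes of other tissues. They were tested with camera (preset correlation 0.01) and, for movement in one direction, with fry, and camera was repeated with an estimated correlation. By fry, the microtubule organising centre and kinetochore lists (adjusted p = 0.0347 for each) and the cohesin list (0.044) stood higher than in the cytoplast. As fry tests against no change, this takes in the array-wide shift of bright probe sets, and by camera none of the 3 passed with an estimated correlation (adjusted p = 0.873 for each) or after cyclic loess (0.194, 0.421 and 0.651). Array measures were compared with exact two-sided permutation tests, for which 3 against 3 arrays cannot go below 0.1.

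The rule for named genes was the 8 largest rises and 8 largest falls with no overlap of arrays among genes past the threshold in each comparison with the SCC (unnamed clones skipped), the 4 members of each list with the smallest p against the cytoplast, and 11 genes set in advance. The genes in the text are a part of those it gave, picked for length after their values were seen. Of the 11, Ccnb1 had no probe set listed with 1 gene and Gapdh none that was kept, so neither was tested. A named gene was taken as above background on an array where it exceeded the 95th percentile of the genes of other tissues there (intensity 68.4 to 102), a level from the planned filters whose use for folds was chosen after values were seen. Where a group had no array above it, the fold is a lower bound, the mean of the brighter group against the mean of the dimmer with each array set to at least that level; no fold is given where both groups were below it or the bound was under 1. No other kept probe set of a named gene passed in the opposite direction.

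The labels do not say whether arrays with the same replicate number came from 1 pool of oocytes. Residuals of arrays with the same number correlated at 0.0215 on average over 8 pairs (-0.304 to 0.614), which does not settle it. The controls spiked in at hybridisation were cut at their largest gap into 4 brighter arrays (cytoplast 4, MII oocyte 2 and 4, SCC 3) and 6 dimmer ones. Cytoplast 1 (mean log2 10.683) lay almost midway between the nearest brighter (11.109) and nearest dimmer array (10.269), so its place is uncertain. No label names a batch. The control level was used as a covariate, and the cut, called a batch here, as a block and for values within batches. All of these were chosen after seeing the data. Controls that would be added before amplification lay at background on all arrays.

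On simulated data for the SCC against the cytoplast with 23737 probe sets, the test recovered 18% of changes of 0.5 on the log2 scale, 76% of changes of 1, and 100% of changes of 1.5 and of 2, and 5 of 152 calls were of unchanged probe sets. The simulated noise was independent between probe sets, without correlated genes, a brightness trend or a batch. These rates hold for that setting and may not hold for the real arrays. Alternatives covered the filter, scaling, variance model, arrays in the fit, replicate block, threshold, probe sets per gene and each array left out. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.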

Results

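Transcript levels were measured in mouse oocytes arrested at metaphase of the second meiotic division (MII), on 1-colour arrays of 45101 probe sets. 3 kinds of sample were compared. The spindle-chromosome complex (SCC), which is the meiotic spindle with the chromosomes and the material around it, was taken out of the oocyte by microsurgery (3 arrays). The cytoplast is the oocyte that remains after that removal (4 arrays), and the intact MII oocyte holds both parts (3 arrays). The design asks whether some maternal transcripts are concentrated at the spindle. The median intensity of an array lay between 15.6 and 16.6, and the 95th percentile between 521 and 788. The number of arrays limits the precision. The labels call the arrays biological replicates without naming animals or pools of oocytes, so p-values measure the spread between these samples.

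A set of transcripts stood at a higher relative level in the SCC than in the cytoplast. Atad2, a chromatin-binding ATPase, had an intensity of 423.5 ± 56.7 (SD, n = 3) in the SCC and 102.1 ± 15.7 (SD, n = 4) in the cytoplast, 4.16-fold higher (log2 difference 2.06, SE 0.19, adjusted p = 0.00128). Cep290, a protein of centrosomes and cilia, was at 118.2 ± 25.7 in the SCC and not well above background on any cytoplast array (34.2 ± 5.9), so at least 1.46-fold higher (adjusted p = 0.00216). Anln, the actin-binding protein anillin of the cytokinetic ring, was at 7502 ± 826 in the SCC and 3366 ± 439 in the cytoplast, 2.23-fold higher (log2 1.16, SE 0.14, adjusted p = 0.00283). Another, dimmer probe set of Anln was 3.54-fold higher (adjusted p = 0.00128). Of the 60 genes named here that passed the limma test in this comparison, 18 passed whichever array was left out, and 15 of these also passed after cyclic loess and after quantile normalization. The 15 were Anln, Atad2, Slc35b3, C1galt1c1, Cep290, Cenpe, Sgo2a, Haus4, Ube2c, Eif5b, Cpeb4, Atrx, Spcs2, Pdia6 and Rpn1, all higher in the SCC.

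**Figure D1:**
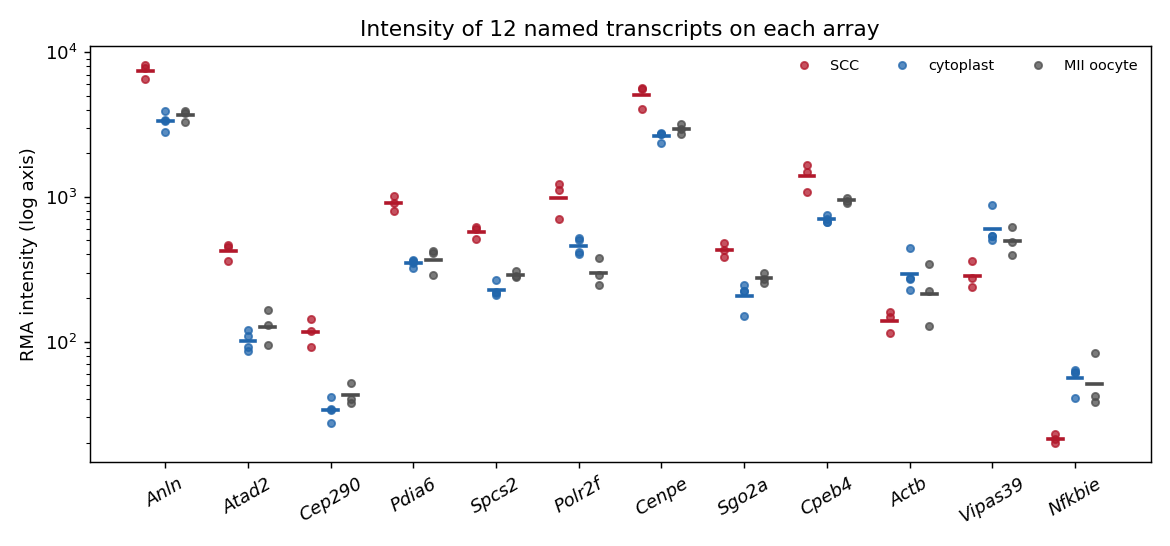
Intensity (logarithmic axis) of 12 transcripts on each array; points are arrays, and short lines are group means of the log2 values, for the SCC (3 arrays), the cytoplast (4) and the intact MII oocyte (3). For Anln the SCC arrays lie above all cytoplast arrays, with mean intensities of 7502 and 3366, while for Nfkbie they lie below them, with 21.4 and 56.7. Nfkbie is not well above background on any array of these groups.

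Over all 23737 probe sets tested, 1599 were higher and 65 lower in the SCC than in the cytoplast, which is 96.1% higher, and at the level of 12713 genes 1123 were higher and 40 lower. Over all probe sets tested, 13.9% were higher and 5.89% lower with no overlap between the arrays of the 2 groups, where chance gives 2.86% each way. Of the calls, 211 of the 1599 and 26 of the 65 were not well above background on any array of either group. This split depended on scaling: 505 were higher and 121 lower after cyclic loess (80.7% higher), and 418 and 154 after quantile normalization (73.1% higher). Of the 1599, 411 passed in the same direction under all 3 scalings (356 named genes), and so did 40 of the 65 (33 named genes). Probe sets with a mean log2 intensity above 8 (3944 of them) stood 0.28 higher in the SCC at the median, 0.02 after cyclic loess and -0.0018 after quantile normalization, whereas the median of all probe sets tested was 0.01. The counts also moved with single arrays. Higher calls numbered 243 without SCC replicate 3, 271 without SCC replicate 2, 578 without cytoplast replicate 1 and 678 without cytoplast replicate 2. Lower calls numbered 1 without SCC replicate 2, 2 without SCC replicate 3, 7 without cytoplast replicate 1, 10 without cytoplast replicate 2, 43 without cytoplast replicate 3, 104 without cytoplast replicate 4 and 191 without MII oocyte replicate 3.

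**Figure D2:**
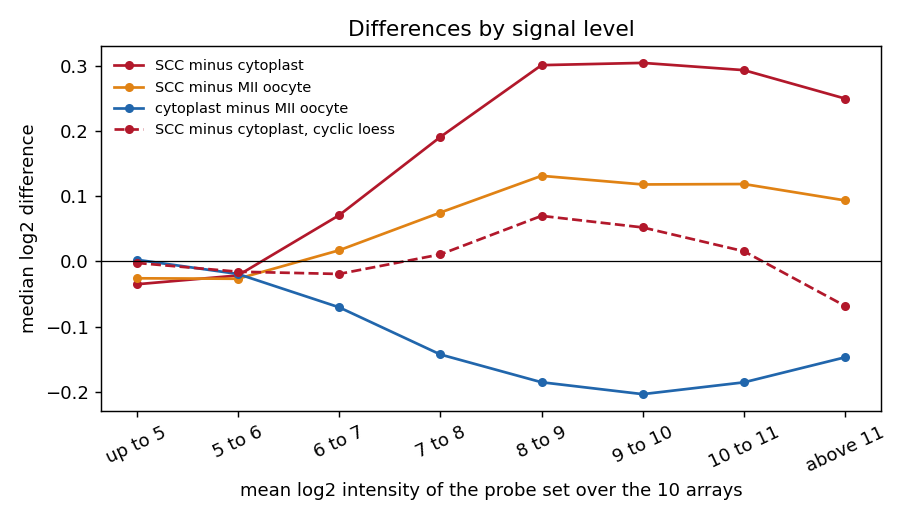
Median log2 difference between groups (vertical axis) for probe sets sorted by their mean log2 intensity over the 10 arrays (horizontal axis); each line is 1 pair of groups, and the dashed line is the SCC minus the cytoplast after cyclic loess. Above a mean log2 of 8 the SCC stood 0.28 above the cytoplast at the median and 0.02 after cyclic loess.

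The largest rises among genes whose arrays did not overlap were those of Tm2d1 (4.43-fold, adjusted p = 0.0121), Atad2, Slc35b3, a transporter of the nucleotide-sulphate donor of the Golgi (4.09-fold, adjusted p = 0.00376), and Atp6v1g1, a subunit of the proton pump of acidic vesicles (4.0-fold, adjusted p = 0.0277). Mis18a, which helps load the centromere histone, was 3.96-fold higher (adjusted p = 0.0396). C1galt1c1 (3.94-fold), Ppp1r15b (3.78-fold) and Cox17, a copper chaperone of mitochondria (3.49-fold), followed. Of these 8, Atp6v1g1, Mis18a, Ppp1r15b and Cox17 missed the threshold after cyclic loess or quantile normalization. Some cytoplast arrays were not above background: 3 of 4 were above it for Atad2 and C1galt1c1, 2 for Tm2d1 and Ppp1r15b and 1 for Cox17. Without SCC replicate 2, as without SCC replicate 3, only Atad2, Slc35b3 and C1galt1c1 of the 8 passed. Of the 8 falls named by the same rule, Vipas39 was above background on all arrays of both groups (290.2 ± 61.6 in the SCC and 611.8 ± 175 in the cytoplast, log2 -1.06, SE 0.22, adjusted p = 0.0172). Bsdc1 (log2 -1.15, adjusted p = 0.0278), Ift122 (log2 -1.03, adjusted p = 0.0314) and the non-coding RNA Snhg3 (log2 -0.97, adjusted p = 0.0421) were above it on 1, 1 and 2 of 3 SCC arrays. Rnf122 was above it on no SCC array and at least 1.65-fold lower there (adjusted p = 0.0328). No fold is given for Nfkbie (adjusted p = 0.0105) and Tdrd3 (adjusted p = 0.0461), not well above background on any array of either group, or for Ipo4 (adjusted p = 0.043), above it on 1 cytoplast array. Ipo4 and Tdrd3 missed the threshold after both other scalings, and none of these 8 falls passed without SCC replicate 2 or without SCC replicate 3.

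Among the lists fixed before the data were examined, 7 of 18 stood higher in the SCC than in the cytoplast by the camera test. Of 42 kinetochore and spindle checkpoint genes measured, 10 were higher and none lower (14 higher and 2 lower adjusted over the list alone), with a median log2 difference of 0.27 (camera adjusted p = 0.00764). With an estimated correlation its adjusted p = 0.873. Cenpe, the kinetochore motor, was 1.91-fold higher (log2 0.93, SE 0.14, adjusted p = 0.00554), Dsn1 1.83-fold, Cenph 1.96-fold and Spdl1 1.74-fold. Of 29 genes of the microtubule organising centre, 6 were higher and none lower (11 higher adjusted over the list alone), with a median of 0.28 (camera adjusted p = 0.00764, and adjusted p = 0.873 with an estimated correlation). They included Cep290, Pcm1 (1.63-fold), Plk4, the kinase of centriole assembly (1.57-fold), and Cep55 (1.5-fold). Of 29 cohesin, condensin and shugoshin genes, 6 were higher and none lower (8 higher adjusted over the list alone), with a median of 0.37 (camera adjusted p = 0.0338, and adjusted p = 0.873 with an estimated correlation). Sgo2a, a protector of centromeric cohesin, was 2.07-fold higher (adjusted p = 0.0064), Ncapg2 1.7-fold, Smc4 2.37-fold and Top2b 2.84-fold.

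Genes outside the spindle's own machinery also stood higher. Of 50 oocyte-specific and maternal-effect genes, 8 were higher and none lower (10 higher adjusted over the list alone), with a median of 0.34 (camera adjusted p = 0.00764, and adjusted p = 0.873 with an estimated correlation). Examples were Nlrp9a (1.89-fold, adjusted p = 0.0174) and the receptor Kit (1.8-fold, adjusted p = 0.0235; above background on 2 of 4 cytoplast arrays), while the egg coat gene Zp3 (log2 0.51, adjusted p = 0.429) and the growth factor gene Gdf9 (log2 0.47, adjusted p = 0.145) did not pass. Of 62 nuclear-encoded genes of oxidative phosphorylation, 6 were higher and none lower (14 higher adjusted over the list alone; median 0.18, camera adjusted p = 0.0333, and adjusted p = 0.873 with an estimated correlation), including Atp5c1 (1.94-fold) and Ndufb3 (1.84-fold). Of 46 endoplasmic reticulum and secretion genes, 7 were higher and none lower (9 higher adjusted over the list alone; median 0.16, camera adjusted p = 0.048, and adjusted p = 0.873 with an estimated correlation). Spcs2 and Sec11a, subunits of the signal peptidase, were 2.53-fold and 2.02-fold higher, Pdia6, a protein disulphide isomerase, 2.6-fold, and Rpn1, which belongs to the oligosaccharyl transferase, 2.88-fold (adjusted p = 0.00128, 0.0117, 0.00234 and 0.00373). Of 39 cytosolic ribosomal protein genes, 5 were higher and none lower (6 higher adjusted over the list alone; median 0.26, camera adjusted p = 0.048, and adjusted p = 0.873 with an estimated correlation), including Rps14 (1.89-fold) and Rplp2 (1.71-fold). None of the 7 lists passed after cyclic loess (adjusted p from 0.194 to 0.827). The mean difference from the other genes went from 0.21 to 0.16 for the microtubule organising centre, 0.21 to 0.11 for the kinetochore, 0.20 to 0.12 for oxidative phosphorylation, 0.20 to 0.09 for cohesin, 0.18 to 0.08 for the endoplasmic reticulum, 0.15 to 0.09 for ribosomal proteins and 0.21 to 0.05 for oocyte-specific genes. None passed when only probe sets above the 75th percentile were used (adjusted p from 0.248 to 0.555), with differences, in the same order, of 0.20, 0.15, 0.13, 0.17, 0.16, 0.09 and 0.13. Without SCC replicate 3, 3 lists passed: kinetochore, microtubule organising centre and oocyte-specific genes. These passed without any other array as well (highest adjusted p 0.0163, 0.0247 and 0.0325). The cohesin list was lost without SCC replicate 3 (adjusted p = 0.0981), and oxidative phosphorylation without SCC replicate 2 or 3 (up to 0.0733). The ribosomal list was lost without cytoplast replicate 1, 2 or 3, MII oocyte replicate 4, SCC replicate 1 or 3 (up to 0.383), and the endoplasmic reticulum list without these or SCC replicate 2 (up to 0.0981).

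**Figure D3:**
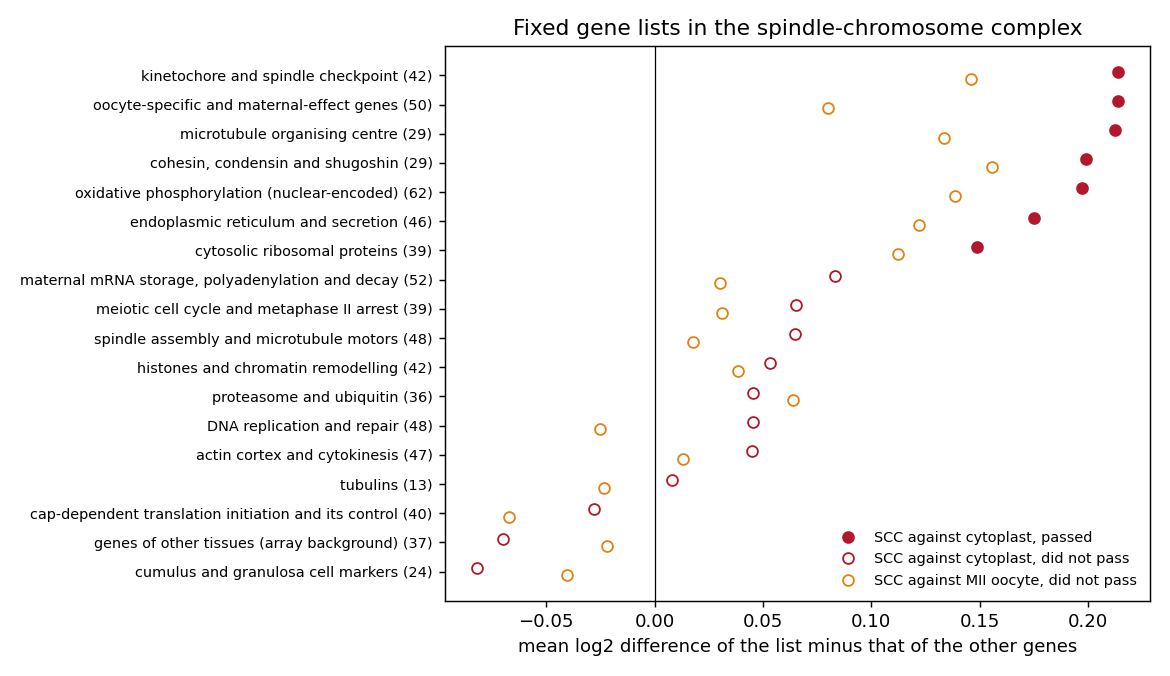
Mean log2 difference of each fixed gene list minus that of the other genes (horizontal axis), in the SCC against the cytoplast and against the intact MII oocyte; the number in brackets is the number of genes measured, and filled points passed the camera test at an adjusted p under 0.05. The kinetochore list has a median log2 difference of 0.27 against the cytoplast, and none of the lists passed against the MII oocyte.

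The other lists did not pass against the cytoplast, though single members did. Spindle assembly and microtubule motors had 6 of 48 higher (6 adjusted over the list alone), among them Haus4 (1.8-fold, adjusted p = 0.00642), Haus3 (1.83-fold), Kpna2 (2.34-fold) and Kif2a (2.03-fold), with a median of 0.14 (camera adjusted p = 0.333). Aurka (log2 0.21, adjusted p = 0.699) and Tpx2 (log2 -0.11, adjusted p = 0.907) did not pass, and their signs turned under some settings. None of 13 tubulin genes passed (camera adjusted p = 0.94; the median of 0.05 and mean of 0.1 were positive, while camera ranked the list below the other genes), and Tubb2a, the member with the smallest p, had a log2 difference of 0.99 (SE 0.3, adjusted p = 0.0716). Of 39 meiotic cell cycle genes 3 were higher (3 adjusted over the list alone; camera adjusted p = 0.333): Ube2c, the ubiquitin-conjugating enzyme of the anaphase-promoting complex (adjusted p = 0.00471; above background on 1 SCC array and no cytoplast array), Cks2 (1.47-fold) and Cks1b (1.37-fold). The kinase Mos did not pass (log2 0.71, SE 0.5, adjusted p = 0.493). In the translation initiation list 2 of 40 were higher (2 adjusted over the list alone; camera adjusted p = 0.914), Eif5b (2.63-fold) and Rheb (1.59-fold), and the repressor Eif4ebp1 did not pass (log2 -0.52, SE 0.34, adjusted p = 0.446). The median of this list was 0.03 and its mean 0.07, while camera ranked it below the other genes. Of 52 genes of mRNA storage, polyadenylation and decay 3 were higher and 1 lower (6 and 1 adjusted over the list alone; camera adjusted p = 0.34): the polyadenylation regulators Cpeb4 (1.99-fold) and Cpeb3 (2.58-fold), the germ cell RNA-binding protein Dazl (1.55-fold), and the helicase Ddx6, which was lower (adjusted p = 0.0337; above background on 1 cytoplast array and no SCC array).

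Of 42 histone and chromatin genes 6 were higher (7 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.521), including Atrx (3.34-fold), Hdac2 (2.48-fold) and Cbx1 (1.71-fold). Of 47 actin cortex and cytokinesis genes 5 were higher (6 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.431), including Anln, Capza2 (1.77-fold) and Cdc42 (2.02-fold). Actb, beta-actin, went the other way without passing (log2 -1.08, SE 0.3, adjusted p = 0.0557) and passed after cyclic loess (log2 -1.28, adjusted p = 0.0377). Of 36 proteasome genes 6 were higher (7 adjusted over the list alone; camera adjusted p = 0.431), including Psma2 (1.97-fold) and Psmd12 (adjusted p = 0.0202; not well above background in either group). Of 48 DNA replication and repair genes 1 was higher, Gmnn, the inhibitor of replication licensing (1.65-fold; none adjusted over the list alone; camera adjusted p = 0.431). None of 24 cumulus and granulosa cell markers passed (median -0.02, mean 0.02, camera adjusted p = 0.34), camera ranking the list below the other genes, the member with the smallest p being Kitl (log2 0.73, SE 0.28, adjusted p = 0.156; above background on 3 of 4 cytoplast arrays). None of 37 genes of other tissues passed (median -0.0018, mean 0.03, camera adjusted p = 0.35, ranked below the other genes), and Cpa1 had a log2 difference of 0.75 (adjusted p = 0.0768). Its intensity was 5964 in the SCC and 3610 in the cytoplast, so not every gene of this list was dim. Of the other genes named in advance, Bub1b (log2 0.22, adjusted p = 0.633) and Plk1 (adjusted p = 0.431; not well above background in either group) did not pass.

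RNA quality and brightness were compared between the groups, and no measure had an exact permutation p under 0.05 between the SCC and the cytoplast. The difference between the 3′ and 5′ beta-actin control probe sets was 3.42 ± 0.201 (log2, SD, n = 3) in the SCC and 4.62 ± 0.687 (n = 4) in the cytoplast (exact two-sided permutation p = 0.0571, where 0.0286 is the smallest possible), and 3.85 ± 0.544 (n = 3) in the MII oocyte. The corresponding Gapdh difference was 2.87 ± 0.48 in the SCC and 3.17 ± 0.556 in the cytoplast (exact permutation p = 0.429, n = 3 and 4). Between the 3′ and middle beta-actin control probe sets the difference was 2.71 ± 0.153 in the SCC and 3.55 ± 0.402 in the cytoplast (exact permutation p = 0.0571, n = 3 and 4). For both beta-actin measures every SCC array lay below every cytoplast array, so comparable RNA quality is not shown. Actb itself was dimmer in the SCC than in the cytoplast (log2 -1.08). These measures therefore do not tell a difference in RNA quality from one in the level of that transcript. The 95th percentile of intensity was 712 ± 86.5 in the SCC, 574 ± 45.1 in the cytoplast and 648 ± 74.4 in the MII oocyte (SCC against cytoplast, exact permutation p = 0.0571, n = 3 and 4). The 15 measures compared this way per pair of groups were not adjusted for their number.

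Against the intact MII oocyte, 10 probe sets were higher in the SCC and none lower, and the same 10 were higher than in the cytoplast. They represent Atad2 (3.32-fold, log2 1.73, SE 0.2, adjusted p = 0.0239), Polr2f, a subunit shared by the RNA polymerases (3.3-fold, log2 1.72, SE 0.22, adjusted p = 0.0239), Cep290 (at least 1.45-fold, adjusted p = 0.0319; not well above background on any MII oocyte array), Pdia6 (2.47-fold, adjusted p = 0.0239), Anln (2.04-fold, adjusted p = 0.0416; 2 probe sets) and Spcs2 (1.99-fold, adjusted p = 0.0262). The rest were single probe sets of Atrx (mean intensity in the MII oocyte below background) and Cdc37l1 (below background in both groups) and 1 without a listed gene, which were outside the rule for named genes and chosen after their values were seen. Those of Cep290, Pdia6, Spcs2 and Atrx missed the threshold after quantile normalization. For Polr2f the mean intensity was 460 in the cytoplast and 304 in the MII oocyte, so the intact oocyte lay below both parts. All cytoplast arrays lay above all MII oocyte arrays for it (log2 0.61, limma adjusted p = 0.926). Against the cytoplast its SCC level was 2.17-fold higher. Over all probe sets tested, 8.71% were higher and 5.34% lower with no overlap between the arrays of the 2 groups, where chance gives 5% each way. At an unadjusted p under 0.05, 2871 probe sets differed, and at the gene level 18 genes were higher and none lower. The count rested on single arrays and on the fit. It was 0 with only the arrays compared, 0 without moderation and 0 at an adjusted p under 0.01. It was also 0 without cytoplast replicate 1, MII oocyte replicate 2, SCC replicate 2 or SCC replicate 3, 25 without SCC replicate 1 and 27 without cytoplast replicate 4. Without MII oocyte replicate 3, 444 were higher and 253 lower, and with the level of the hybridisation controls in the fit, chosen after seeing the data, 296 were higher and 15 lower. No list passed (kinetochore: median 0.15, camera adjusted p = 0.0561). Of the members, 2 endoplasmic reticulum genes, 1 microtubule organising centre gene and 1 actin cortex gene were higher (5 higher and 1 lower, 3 higher, and 1 higher adjusted over the list alone). Adjusted over the list alone, 10 kinetochore genes were higher and 1 lower, 4 proteasome genes higher and 1 lower, and 4 cohesin genes higher. So was 1 gene each of the meiotic cell cycle, translation initiation, ribosomal and chromatin lists. DNA replication and repair genes had a positive median (0.04) and mean (0.01) while camera ranked them below the other genes (adjusted p = 0.672).

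Both comparisons share the SCC arrays. A simulation of unchanged groups gave 0 probe sets higher than both. As no group differed in it, few calls could arise, so it does not show what the shared SCC arrays add to the overlap. Independent lists would share 0.674. The simulated values were also independent between probe sets, without array-wide structure. The 2 sets of differences correlated at 0.84 across probe sets, which are not independent replicates, against 0.535 in the simulation, and their covariance was 0.0797 against 0.0182, a difference of 0.0615. These differences were not compared with separate SCC arrays on each side. Part of the excess may therefore come from array-wide structure of the shared SCC arrays, which the simulation lacked. The sign was the same for 78.4% of all probe sets tested, against 67.9% in the simulation.

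Between the cytoplast and the intact MII oocyte, limma found 0 probe sets higher and 0 lower, and 1054 differed at an unadjusted p under 0.05. The count was also 0 with every other scaling, filter, variance model and threshold, and with each array left out. Among the 6 arrays with dimmer hybridisation controls alone, chosen after seeing the data and holding 1 MII oocyte array (replicate 3), 130 were higher and 63 lower. Atad2 had a log2 difference of -0.32 (adjusted p = 0.926) and Anln -0.13 (adjusted p = 0.929). Of the lists, the 50 oocyte-specific and maternal-effect genes stood lower in the cytoplast with no member passing (median log2 -0.19, camera adjusted p = 0.0112, and adjusted p = 0.94 with an estimated correlation). This call was lost after cyclic loess (adjusted p = 0.987), above the 75th percentile (0.318), with the hybridisation control level in the fit (0.0723), and without cytoplast replicate 2 (0.13), cytoplast replicate 3 (0.0534) or MII oocyte replicate 4 (0.278).

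An intact oocyte is the sum of both parts, so the difference of the SCC from the cytoplast and that of the MII oocyte from the cytoplast were compared across 12713 genes. With separate cytoplast arrays on each side, the correlation averaged 0.316 over 6 ways of dividing them (0.093 to 0.425), and the mean slope was 0.185. Genes are not independent replicates, and after cyclic loess the mean correlation was 0.246 (0.00522 to 0.355).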

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

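The count of calls that passed under all scalings, the controls of amplification, the hybridisation batch, the lists matched on level, the probe types and the other probe sets of a gene are tests chosen only after the results were seen, as were the test of the cumulus markers and the bounds for it and for the estimated correlation. 8 of the values checked in the 4 cytoplast arrays stood apart from the other 3 arrays by Dixon's test, out of 73 genes and 15 array measures; chance gives about 1 in 20. On cytoplast replicate 4, Tm2d1 had a log2 intensity of 7.303 (157.9 against 68.4 to 77.3 on the others), Ube2c 5.101 (34.3 against 22.0 to 22.6) and Psma2 10.96 (1987 against 1350 to 1432). On cytoplast replicate 2, Nfkbie had 5.351 (40.8 against 60.6 to 63.7) and Cenpe 11.21 (2370 against 2712 to 2771). On cytoplast replicate 3, Rheb had 12.17 (4604 against 3554 to 3705) and Sec11a 10.57 (1519 against 1215 to 1228). Vipas39 had 9.768 on cytoplast replicate 1 (872.2 against 499.6 to 538.9).

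The first pattern is that calls against the cytoplast were mostly higher in the SCC. Array-wide brightness of expressed transcripts is argued against as the cause of all the higher calls, since 25.7% of them passed under both other scalings. Those calls are defined by passing, and nothing independent of that was tested on them. Cyclic loess also left a small trend by level. The median difference of the SCC from the cytoplast was then 0.07 at a mean log2 of 8 to 9 and -0.07 above 11. For the calls that ended, the median of bright probe sets fell from 0.28 to 0.02 after cyclic loess, and because the controls that would be added before amplification lay at background (log2 at most 2.86), brightness of the arrays and a broad enrichment at the spindle cannot be told apart. The hybridisation batch is argued against, since all 1599 higher calls passed with the control level in the fit, and the 6 dimmer arrays alone gave 1816 higher and 368 lower calls. RNA from cumulus cells is argued against as the whole cause. The 42 markers on the array had an upper quartile of 1.39 for the gain in intensity, against a lower quartile of 59.9 for the higher calls. Those calls were picked for their rise in these data, which widens the gap. Of the 24 markers tested, 20 were above background on no array. Of the oocyte-specific genes, which such RNA would dilute, 8 were higher and none lower, but that list did not pass after cyclic loess (camera adjusted p = 0.827). None of the 24 markers tested passed, the smallest p being that of Kitl (log2 difference 0.73, adjusted p = 0.156), and a small part is not excluded. A concentration of transcripts at the spindle and a difference in RNA quality (exact p = 0.0571 for the 3′ to 5′ actin difference) stay open, the biological explanation being untested.

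The second pattern is that the kinetochore and microtubule organising centre lists stood higher. Their medians lay at percentiles 95.9 and 99.03 of random lists of the same size matched on level, and those of the oocyte-specific genes (98.17), ribosomal proteins (98.07) and cohesin list (99.37) lay above the first of these, so the excess was not particular to the spindle. The oxidative phosphorylation (87.35) and endoplasmic reticulum (69.54) lists, which also passed camera, lay lower. After cyclic loess the mean difference of the kinetochore list from the other genes fell from 0.21 to 0.11 (unadjusted p = 0.0924, adjusted p = 0.421) and that of the microtubule organising centre list from 0.21 to 0.16 (unadjusted p = 0.0108, adjusted p = 0.194), with an SD over genes of 0.44 in both as deposited. The calls ended on smaller differences, more of the first than of the second was taken away, and a p that misses the threshold does not speak for brightness by itself, so brightness and a shift of these genes cannot be told apart. Genes that vary together between arrays may account for the calls: with an estimated correlation, 0.106 and 0.149 in place of the preset 0.01, the smaller unadjusted p was 0.115. A concentration of such transcripts at the spindle stays open as a hypothesis.

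The third pattern is that the 65 lower probe sets were more often of the types that can share probes with related transcripts (30.8%, against 12.4% of the others, odds ratio 3.13, Fisher's exact p = 8.34e-05). Of 21 genes with other probe sets of a mean log2 above 6, those of 57.1% also fell (exact 95% interval 34.0 to 78.2), against 30.3% of the probe sets of other genes. The interval lies above 30.3% but spans 50%, the bound chosen for this test. With 21 genes, how far shared probes account for these calls cannot be told. For the 121 lower calls after cyclic loess, which include 40 of the 65, shared probes are argued against as the whole cause. Of 49 such genes the other probe sets of 77.6% fell (exact 95% interval 63.4 to 88.2), against 48.7% of the probe sets of other genes.

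Of the 35 splits of the SCC and cytoplast arrays into groups of these sizes, 1, the real one with 1664 calls, gave as many, and the highest other gave 0. This share is under 0.05, but 35 splits allow none smaller, so chance in the grouping is argued against and not excluded. Every other split puts SCC and cytoplast arrays in 1 group, so a real difference adds to its spread and lowers its count. Of the 10 splits of the SCC and MII oocyte arrays, 1, the real one with 10 calls, gave as many and the highest other gave 0, and 10 splits are too few for a share under 0.05. For the cytoplast and MII oocyte the real count was 0, which each of the 35 of 35 splits reaches by definition, so the splits decide nothing. The highest other split gave 1873 calls. It set cytoplast 1 and 4 and MII oocyte 2 and 4 against the rest, which was the split with the largest gap in hybridisation controls and points to a technical structure of these arrays. With the batch as a block the real comparison gave 0 calls. Counts within the 6 dimmer or the 4 brighter arrays decide nothing here. The dimmer hold 1 MII oocyte array (replicate 3) and the brighter 1 cytoplast array, and 1 array has no spread of its own.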

How the results depend on the processing

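The fits with the hybridisation controls, the values within the dimmer arrays and cyclic loess for the mass balance were chosen after seeing the data; the other alternatives in this part were planned. Arrays limit the lower end: probe sets near background have little signal over it. Counts for the SCC against the cytoplast are given as higher and lower, then those against the MII oocyte, then those past both. Without a filter, those against the MII oocyte and past both were 16 and 16, and 1 list passed against the MII oocyte. Above the 75th percentile 0 lists passed against the cytoplast. Quantile normalization gave 418 and 154, 6 and 6, and cyclic loess 505 and 121 with 0 lists against the cytoplast. Median centring gave 16 and 16. Array quality weights gave 3030 and 482, 391 and 85, 380 and 60. With the arrays compared alone 1879 were higher and 185 lower, and 0 passed against the MII oocyte and 0 both. Requiring at least 2-fold gave 373 and 10, an adjusted p under 0.01 gave 285 and 2, 0 and 0. The mean of the probe sets of a gene gave 1007 and 41 genes, 22 and 22, with 2 lists against the MII oocyte. No moderation gave 273 and 6, 0 and 0. With an estimated correlation 0 lists passed against the cytoplast. The hybridisation control covariate gave 2767 and 293, 296 and 15, 284 and 11, and the batch as a block 2525 and 251, 308 and 19, 289 and 9. Only the 6 dimmer arrays gave 1816 and 368. The causes were not tested, except that fewer units or arrays enter some of these fits. The mean correlation of the mass balance stayed between 0.246 and 0.316. Single divisions of the cytoplast arrays varied more, from 0.093 to 0.425 as deposited and from 0.00522 to 0.355 after cyclic loess.

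With the replicate number as a fixed block, 1834 were higher and 110 lower than in the cytoplast, 125 higher and 14 lower than in the MII oocyte, 123 and 13 past both, and 3 lists passed against the MII oocyte. Whether the numbers mark shared pools of oocytes is not settled by the residuals (mean correlation 0.0215). As a random block, with a correlation of -0.00135, no call of a named gene changed.

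Leaving out each array gave, against the cytoplast, 243 to 2044 higher and 1 to 191 lower, with 3 to 7 lists. Against the MII oocyte it gave 0 to 444 higher and 0 to 253 lower, with 0 to 2 lists, and 0 to 415 higher and 0 to 94 lower past both. Against the cytoplast the low ends of the counts came from leaving out SCC replicate 2 or 3 and the high ends from MII oocyte replicate 3, which also gave the high ends against the MII oocyte and past both. Ranges that crossed 0 were those of Tpx2 (-0.25 to 0.12), tubulins (-0.0424 to 0.0414) against the cytoplast, and, against the MII oocyte, DNA replication and repair (-0.0478 to 0.000269), meiotic cell cycle (-0.0508 to 0.0746), mRNA storage (-0.0141 to 0.0714), histones and chromatin (-0.00998 to 0.0726), actin cortex (-0.0843 to 0.0702) and tubulins (-0.0741 to 0.0222). Of the 66 named calls, 36 passed after cyclic loess, 28 after quantile normalization, 19 without moderation, 18 without SCC replicate 2 and 19 without SCC replicate 3.

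Signs turned as follows, none of them of a value past the threshold, and the cause was not tested. Aurka had -0.0358 after quantile normalization and Bub1b -0.125 after cyclic loess. Tpx2 had 0.00633 with array weights, 0.0721 with the replicate block and 0.022 in the 6 dimmer arrays. List means minus other genes, against the cytoplast, above the 75th percentile: tubulins -0.0339, mRNA storage -0.0168, histones and chromatin -0.00138, DNA replication and repair -0.0446. After cyclic loess: spindle assembly -0.0259, meiotic cell cycle -0.0137, mRNA storage -0.0211, proteasome -0.00776, histones and chromatin -0.0304, actin cortex -0.0484, DNA replication and repair -0.0522. With the mean of probe sets, translation initiation 0.0145. Against the MII oocyte, above the 75th percentile: mRNA storage -0.0329, genes of other tissues 0.00427. After cyclic loess: spindle assembly -0.0225, meiotic cell cycle -0.0037, mRNA storage -0.0156, actin cortex -0.0279, genes of other tissues 0.00876. Tubulins had 0.0298 with the replicate block, 0.0384 with the mean of probe sets and 0.0126 with the covariate, and DNA replication and repair 0.0049 with the mean of probe sets.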

Other observations

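The tests on gene names in this part were chosen after the results were seen, and that on gene span before. Of the endoplasmic reticulum and secretion genes, Spcs2, Pdia6 and Rpn1 passed against the cytoplast whichever array was left out, and Spcs2 and Pdia6 were also higher than in the intact oocyte (1.99-fold and 2.47-fold). Those 2 calls were less firm: both were lost after quantile normalization (adjusted p = 0.0637 and 0.0633) and without cytoplast replicate 1, MII oocyte replicate 2, SCC replicate 2 or SCC replicate 3 (up to 0.195), and that of Spcs2 also without cytoplast replicate 2 or MII oocyte replicate 4. The list as a whole had a camera adjusted p = 0.048, an adjusted p = 0.873 with an estimated correlation and 0.651 after cyclic loess. Where the endoplasmic reticulum lay in these MII oocytes was not measured. If some of it lay at the spindle, transcripts translated at it may have been taken out with the complex. As a wider test of this hypothesis, genes whose names begin with Tmem (162 genes) and Slc (265 genes), most of which encode membrane proteins, were compared with the other genes. The Tmem genes had a median log2 difference of 0.08 from the cytoplast (camera adjusted p = 0.35 over 21 sets) and 0.05 after cyclic loess (unadjusted p = 0.0253, adjusted p = 0.189). The Slc genes had 0.05 (adjusted p = 0.444) and 0.04 after cyclic loess (unadjusted p = 0.0654, adjusted p = 0.328). Neither family passed, and a small shift is neither shown nor excluded.

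The longest 4214 genes (median span 83.9 kb) had a median log2 difference from the cytoplast of 0.0037 after cyclic loess and the shortest 4214 (6.28 kb) -0.0206, a difference of 0.0243, under the bound of 0.1 set beforehand. On the deposited values the medians were 0.06 and -0.01, rising over the 3 groups of genes by span, and the mean log2 intensity rose with them (median 5.26 in the shortest and 6.24 in the longest). A gene span was found for 99.4% of the genes, from the GRCm38.p6 gene table.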
